A study of Mus musculus with 15 samples.

How the data were processed

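The study compared tibial subchondral bone from sham-operated wild-type, DMM-operated wild-type and DMM-operated Pvalb conditional knockout male mice, 5 libraries each. Per the labels' protocols, frozen bone was ground, RNA was enriched for poly(A) and stranded libraries were built with dUTP. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.10a, featureCounts 2.0.3 and the mouse build GRCm39. The values used are FPKM as deposited by the authors, in 1 table for all libraries. The tool that made the FPKM values is not given in the sources used here. The values did not come out as whole reads, so depth could not be recovered and no count test was used. The columns were matched to the samples by name, and 0 columns were left unmatched. No pair among the 105 pairs of libraries was identical. The labels call the libraries biological replicates.

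Of 55335 gene IDs, 55154 were given a symbol and 181 were not; 20401 IDs were at 0 in every library. The annotation available was of another mouse build, so no coordinates are printed. Similarity of AC117239.2 to Hspe1 was measured with BLAST 2.17.0 and overlap of gene models from that annotation.

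Tests were run on log2(FPKM + 1), which understates changes of low genes, for the 13653 genes with at least 1 FPKM in at least 5 of 15 libraries. One limma 3.58.1 fit (R 4.3.3) with a mean for each of 3 groups and an intensity trend gave 3 comparisons, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Single values were tested by exact two-sided permutation over all 252 arrangements of 5 against 5 libraries. The 28 gene lists covered bone, cartilage, signalling, stress, metabolism and the other cell types that dissected bone can hold; 392 of their 393 genes were found. They were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison. The design, these lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Pvalb, up to 10 per direction past the threshold with the largest change, or 5 with the smallest p where none passed, and up to 4 members per list with the smallest p, leaving out unnamed loci. A member of these lists is not reported here. Slc2a3 in the knockout, Hspe1, the Nnt IDs, Gm45222 and Gm26917 were named after their values were seen.

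Tested on simulated data, with 200 changed genes among 13653, the gene test recovered 86.2% of changes of 1 log2 unit and 97.8% of 2 log2 units for DMM against sham with independent noise. With the residuals of whole libraries as noise, it recovered 89.8% and 96.8% in that comparison. The changes were placed at random in genes with a mean log2(FPKM + 1) over 1. The rates are averages over such genes and do not hold for genes that vary more within groups. They also depend on the 200 changed genes: with fewer, a gene needs a smaller unadjusted p to pass, and recovery would be lower. For the list test, 3 lists were shifted by 0.5. With library residuals as noise, the preset correlation also called on average 8.5 of 24 unshifted lists for DMM against sham, 8.2 for knockout against wild-type and 7.3 for knockout DMM against sham. An estimated correlation called 0 of them, and 2.4, 1.6 and 1.8 of the 3 shifted lists. Calls with the preset correlation alone are therefore given beside the estimated one.

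Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, the replicate number as a block, a fit of the 10 libraries compared, robust moderation, a muscle or erythroid covariate, each library left out, other thresholds and an estimated correlation. Added after seeing the data were array weights, leaving out 3 libraries far out on the first principal component, 2 other list tests, Pvalb relative to Ckm, Ckm alone as a covariate, and the muscle covariate with an estimated correlation. A muscle covariate is itself measured in these libraries. Figures were drawn with matplotlib 3.10.9.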

Results

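Gene expression was measured by poly(A) RNA sequencing in subchondral bone of the tibia, the bone plate under the joint cartilage, from 15 male mice in 3 groups of 5. Wild-type mice had a sham operation or destabilization of the medial meniscus (DMM), in which a ligament that anchors the meniscus is transected so that the joint is loaded abnormally and osteoarthritis develops. The remaining group had DMM and carried Dmp1-Cre with floxed Pvalb alleles, a conditional knockout (cKO) aimed at osteocytes, the cells embedded in bone matrix. Surgery was at 8 weeks of age and bone was collected 8 weeks later. A sham-operated knockout group was not analysed here. Values were FPKM, fragments normalised to transcript length and to the library's total, and they summed to between 375453 and 468423 per library. The table gave no read counts, so the depth of each library was unknown. Between 12592 and 13510 gene IDs per library had at least 1 FPKM.

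Pvalb encodes parvalbumin, a calcium-binding protein abundant in fast skeletal muscle, and is the gene targeted in the knockout. Pvalb (ENSMUSG00000005716) was 71.3, 490, 300, 15.8 and 402 FPKM in sham wild-type replicates 1 to 5. It was 132, 95.3, 375, 39.1 and 33 FPKM in DMM wild-type replicates 1 to 5, and 28.7, 23.7, 162, 88.4 and 166 FPKM in knockout DMM replicates 1 to 5. The targeted gene was thus present in every knockout library, and its level did not separate the groups. The log2 difference between knockout and wild-type bones after DMM was -0.38 (SE 0.94; limma adjusted p = 0.95; exact permutation p = 0.659, two-sided, n = 5 per group). Between DMM and sham wild-type bones it was -0.69 (SE 0.94; limma adjusted p = 0.92; exact permutation p = 0.54). That difference ran from -0.26 without sham replicate 2 to -1.48 without sham replicate 4, and was -0.44 and -0.33 without sham replicates 3 and 5 and -1.2, -0.39 and -0.33 without DMM replicates 3, 4 and 5. The direction in the knockout comparison turned to 0.13 without wild-type DMM replicate 3 and came to 0 without knockout replicate 2.

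Pvalb followed the fast skeletal muscle genes across libraries. Its log2 level correlated with the mean of 20 fast muscle genes over the 15 libraries (Pearson r = 0.93, Spearman rho = 0.92, permutation p = 1e-05 for each, the smallest that 100000 permutations can give; 1 relation computed). Without the 2 libraries farthest from the median muscle score r was 0.89, and in the 10 wild-type libraries r was 0.99. Relative to Ckm, the muscle creatine kinase, Pvalb was lower in all knockout libraries. The ratio was 1.13 ± 0.20 (SD, n = 5) in sham wild-type, 1.29 ± 0.27 in DMM wild-type and 0.56 ± 0.19 in knockout DMM bones. Knockout ratios ran from 0.39 to 0.88 and wild-type DMM ratios from 1.04 to 1.73, a log2 difference of -1.23 (exact permutation p = 0.00794, rounded 0.0079 being the smallest possible with 5 against 5). This ratio was chosen after the levels of Pvalb were seen.

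**Figure D1:**
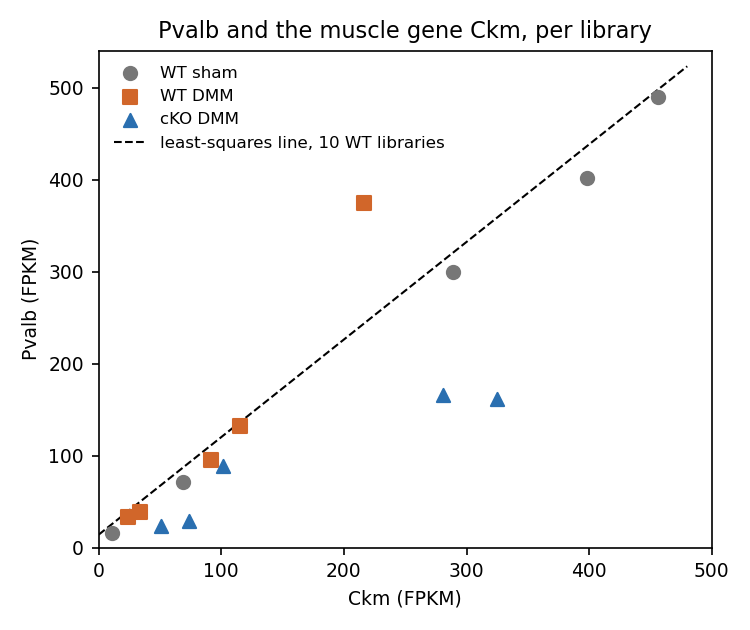
Pvalb (vertical axis, FPKM) against the muscle gene Ckm (horizontal axis, FPKM), 1 point per library, with the least-squares line through the 10 wild-type libraries (slope 1.06). The 5 knockout libraries lie below the line, and the levels of Pvalb itself overlap between the groups.

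The comparison of DMM with sham surgery in wild-type mice asked how loading after meniscus destabilization alters gene expression in this bone. Genes of fibroblasts and connective tissue had higher values after DMM. Col3a1, a fibrillar collagen, was 97 ± 38.6 FPKM after DMM and 16.6 ± 8.61 after sham surgery (SD, n = 5), a ratio of 5.84. Lum, a collagen-binding proteoglycan, was 138 ± 23.8 against 43.6 ± 16.6 FPKM, and Mmp2, a gelatinase, was 54.1 ± 13.6 against 20.2 ± 6.22 FPKM. Tnf, an inflammatory cytokine, was 2.55 ± 0.475 FPKM after DMM and 4.58 ± 0.582 after sham surgery. No single gene passed the test over all genes.

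Of 13653 genes tested, 0 had a limma adjusted p under 0.05, and the smallest adjusted p was 0.142. At an unadjusted p under 0.05 there were 946 genes, 751 higher and 195 lower after DMM, where 683 would be found by chance. The 5 DMM and 5 sham libraries did not overlap for 244 genes, or 1.79%, where chance gives 0.79%. These chance values are averages. Genes vary together across libraries, so counts can lie far above or below them without an effect, here and in the other comparisons. Of 29 other settings tried, 21 also gave 0 genes. The largest count came with the mean of the fast muscle genes as a covariate, 280 genes, 268 higher and 12 lower. That count was 172, 145, 130 and 59 without sham replicates 1, 2, 3 and 4, and 156 and 133 without DMM replicates 1 and 5. It was 247 with Ckm alone as the covariate, a choice made after seeing the data. Array weights, which give less weight to libraries with more scatter and were also chosen after seeing the data, gave 15 genes. The weights were 3.69 for wild-type DMM replicate 5 and 3.237 for knockout replicate 5, and as low as 0.188 for wild-type DMM replicate 3. Results with array weights thus rest largely on 1 library in each DMM group. The remaining settings gave 2 or fewer, among them 1 without DMM replicate 1, 1 without knockout replicate 1 and 2 without knockout replicate 3. With the muscle covariate, 9 of 13 fibroblast genes and 5 of 11 matrix protease genes were higher after DMM with adjusted p under 0.05. Col3a1 then had a log2 difference of 2.93 (SE 0.39, adjusted p = 0.00331), Fmod 2.17 (adjusted p = 0.00331), Lum 1.98 (adjusted p = 0.00353) and Tnf -0.67 (adjusted p = 0.013).

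The genes with the smallest p in each direction are given as not past the threshold in the fit without a covariate. Higher after DMM were Apln, the ligand apelin (log2 difference 0.83, adjusted p = 0.142), Dact3 (0.61, adjusted p = 0.142), the immunoglobulin gene Igkv8-28 (2.66, adjusted p = 0.2), Msx1 (0.56, adjusted p = 0.209) and Dpysl3 (0.67, adjusted p = 0.209). Lower were Tnf (-0.66, adjusted p = 0.142), Mllt3 (-0.66, adjusted p = 0.142), the glucose transporter Slc2a3 (-1.28, adjusted p = 0.216), Cyp2e1 (-1.57, adjusted p = 0.216) and Gpr146 (-0.59, adjusted p = 0.244). Other settings took most of these 10 genes past the threshold: the muscle covariate all except Gpr146 (adjusted p = 0.0397 or less), and array weights Apln, Dact3, Dpysl3, Tnf, Mllt3, Slc2a3 and Cyp2e1 (adjusted p = 0.0468 or less). With 1 library left out, Slc2a3 passed without DMM replicate 1 (-1.53, adjusted p = 0.0434), Apln and Dact3 without knockout replicate 3 (adjusted p = 0.0297 and 0.0494) and Mllt3 without knockout replicate 1 (adjusted p = 0.0494), which also passed with the erythroid covariate (adjusted p = 0.046).

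Among the 28 gene lists, camera with its preset correlation called 12 higher and 1 lower after DMM, and 0 with an estimated correlation. All 13 measured genes of the fibroblast and synovium list were higher, with a median log2 difference of 1.16. Adjusted over the list alone, 10 of the 13 passed, against 0 over all genes tested. The adjusted p of this list was 6.35e-15 with the preset correlation and adjusted p = 0.175 with an estimated correlation. Col6a1 and Col6a2, chains of collagen VI, had log2 differences of 1.37 and 1.55. All 11 matrix protease and inhibitor genes were higher (median 0.67), and 7 passed when adjusted over the list alone; the list had adjusted p = 0.175 with an estimated correlation. They included Mmp3, a stromelysin (log2 difference 1.87), Htra1 (1.7) and Mmp14 (0.67). The 5 tendon and ligament genes were all higher (median 0.98; adjusted p = 0.294 with an estimated correlation), and 3 passed when adjusted over the list alone: Fmod, Scx and Tnmd.

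Differences of bone and cartilage genes were of smaller median. All 18 osteoblast and bone matrix genes were higher (median 0.39; adjusted p = 0.294 with an estimated correlation), and 1, Omd, passed when adjusted over the list alone (21 ± 2.82 against 11.4 ± 4.19 FPKM). Of 10 osteocyte genes, 8 were higher (median 0.27; adjusted p = 0.366 with an estimated correlation), and 1, the gap junction gene Gja1, passed when adjusted over the list alone. Of 15 osteoclast genes, 13 were higher (median 0.21; adjusted p = 0.342 with an estimated correlation), and Oscar and the collagen-degrading protease Ctsk passed when adjusted over the list alone. The cartilage list was not called (median 0.07, adjusted p = 0.176), although Comp and Col10a1 passed when adjusted over the list alone, with log2 differences of 1.47 and 1.48. Called higher with the preset correlation were also mechanosensing (median 0.24; adjusted p = 0.294 with an estimated correlation) and Wnt signalling (0.2; adjusted p = 0.366 with an estimated correlation). So were TGF-beta and BMP signalling (0.09; adjusted p = 0.366 with an estimated correlation) and nerve and axon guidance (0.32; adjusted p = 0.294 with an estimated correlation). The Wnt and TGF-beta lists hold inhibitors as well as activators, so their medians give no direction of signalling. The endothelial list (0.13; adjusted p = 0.366 with an estimated correlation) and the immediate early and heat shock list (0.18; adjusted p = 0.366 with an estimated correlation) were called higher too. Without sham replicate 4, the lists osteocyte, TGF-beta and BMP signalling, nerve and axon guidance, and immediate early and heat shock (handling) were no longer called (adjusted p = 0.0742, 0.0512, 0.0596 and 0.0751). The nerve list was also lost without DMM replicate 1 (adjusted p = 0.0711) and the immediate early list without DMM replicate 2 (adjusted p = 0.108). With no filter the nerve list had a median of 0.03 (adjusted p = 0.0618), and with the stricter filter one of 0.18 (adjusted p = 0.298). With the stricter filter the TGF-beta list was lost too (adjusted p = 0.167). The immediate early list was lost without the 3 libraries farthest out on the first principal component (adjusted p = 0.0609), an alternative added after seeing the data. Medians moved by over 1.5 times for osteocyte genes without sham replicate 4 (0.14), osteoclast genes without DMM replicate 4 (0.11), immediate early genes without sham replicate 1 (0.11) and endothelial genes without sham replicates 3 and 5 (0.08 and 0.21).

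The inflammatory cytokine list was not called (median -0.05, adjusted p = 0.768), and its members went both ways. Adjusted over the list alone, Il1b, Cxcl2 and Tnfsf11 were higher and Tnf lower after DMM. All 20 fast muscle genes were lower after DMM (median -0.78; adjusted p = 0.532 with an estimated correlation), and 0 passed when adjusted over the list alone. This median was -0.38, -1.56 and -0.45 without sham replicates 2, 4 and 5, and -1.2 and -0.47 without DMM replicates 3 and 5, with the list called each time (adjusted p = 0.0445 or less). Their mean log2 level was 4.37 ± 1.05 after DMM and 5.15 ± 1.88 after sham surgery, so these scores differed by less than their SD within the groups. The 13 lists not yet named had adjusted p of 0.0671 or more: calcium handling, slow muscle, erythroid, neutrophil, B cell, T and NK cell, macrophage, megakaryocyte, adipocyte, proliferation, oxidative phosphorylation, glycolysis and senescence.

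**Figure D2:**
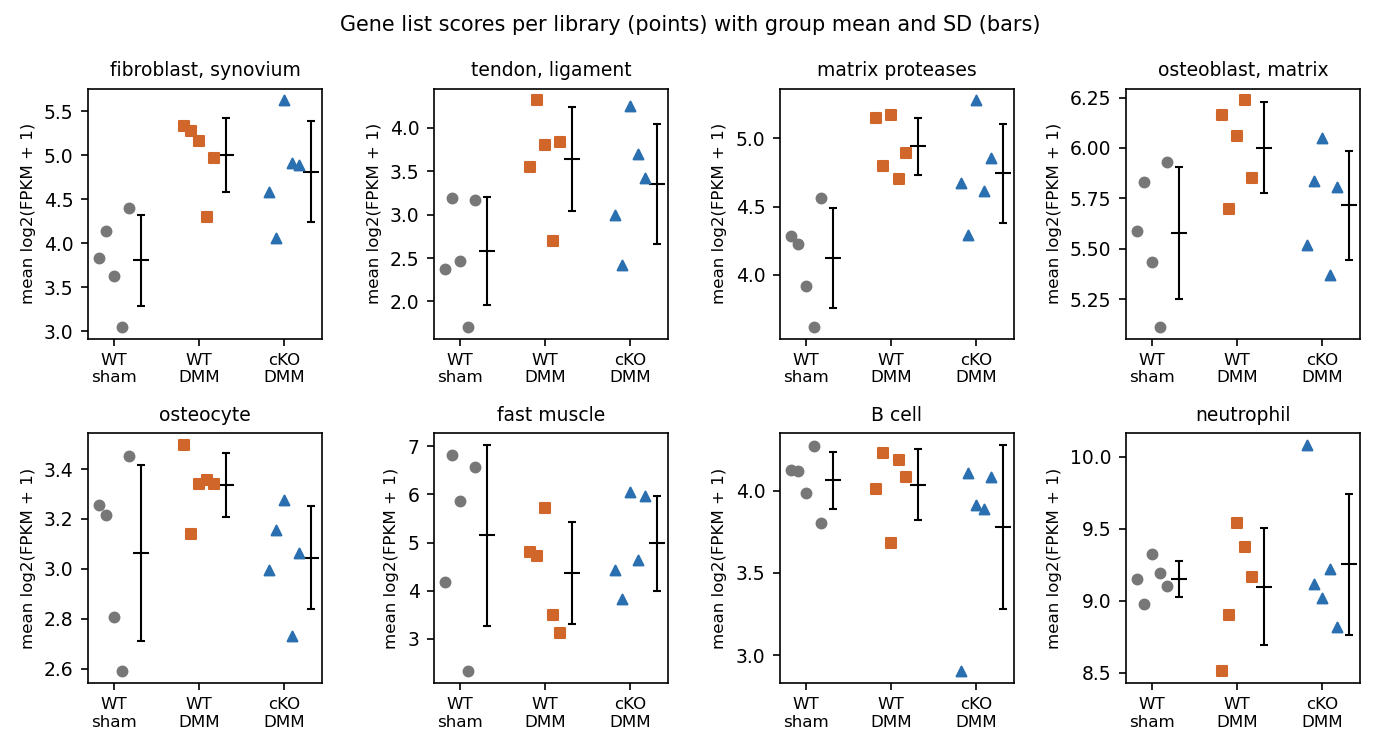
Mean log2(FPKM + 1) of 8 gene lists per library (points) with the group mean and SD (bars), for sham wild-type, DMM wild-type and knockout DMM bones. The fibroblast score was 5.01 ± 0.42 in DMM wild-type and 3.81 ± 0.52 in sham wild-type bones, and the muscle score spread widely within each group.

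The comparison of knockout with wild-type bones after DMM asked what loss of Pvalb in osteocytes changes in the operated joint. Without sham-operated knockout bones, a changed response to DMM cannot be told apart from a genotype difference present without surgery. AC117239.2 (ENSMUSG00000117621) was the 1 gene that rose, to 6.94 ± 1.52 FPKM in knockout from 1.55 ± 0.382 in wild-type bones (SD, n = 5). Its log2 difference was 1.63 (SE 0.14, limma adjusted p = 0.000135), and all 5 knockout libraries, from 5.29 to 9.26 FPKM, lay above all wild-type ones. Its transcript of 515 bases is 99.0% identical to Hspe1, which encodes a mitochondrial chaperonin, so reads could be shared between them and the level is uncertain. A fixed share of Hspe1 reads as the whole cause of the difference is argued against. Hspe1 overlapped between the groups, at 37.1 to 61.7 FPKM in knockout and 27.5 to 61.6 in wild-type DMM libraries. A strain difference between knockout and wild-type mice, raised below for Nnt, was not tested for this gene either. The design does not separate it from loss of Pvalb. Osteocyte genes had lower values in the knockout bones: Sost, the secreted Wnt inhibitor sclerostin, was 16.5 ± 3 against 23.4 ± 3.6 FPKM, and Dkk1 was 4.55 ± 0.645 against 6.72 ± 1.46 FPKM. Neither passed the test (adjusted p = 0.935 for both), and 0 of the 10 osteocyte genes measured passed when adjusted over the list alone. Sham wild-type bones had 24.9 ± 7.97 FPKM of Sost and 4.88 ± 1.81 of Dkk1. Against sham bones, the median log2 difference of the osteocyte list in knockout DMM bones was -0.02.

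At an unadjusted p under 0.05 there were 444 genes, 151 higher and 293 lower in the knockout, fewer than the 683 that chance gives on average. Groups did not overlap for 52 genes, or 0.38%, where chance gives 0.79%. The count of 1 was 2 without wild-type DMM replicate 1. No gene fell, and those with the smallest p among the lower ones were BC055402 (log2 difference -0.52), Igkv8-28 (-1.86), Rcan3 (-0.23), Gstz1 (-0.39) and Apbb1 (-0.32), each with adjusted p = 0.935.

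Camera with the preset correlation called 5 lists higher and 8 lower in the knockout bones, and 0 with an estimated correlation. Of 10 osteocyte genes, 9 were lower (median -0.29; adjusted p = 0.539 with an estimated correlation), among them Phex, with a log2 difference of -0.47. Of 18 osteoblast and bone matrix genes, 17 were lower (median -0.3; adjusted p = 0.539 with an estimated correlation), among them Omd (-0.82) and the osteocalcin genes Bglap (-0.45) and Bglap2 (-0.48). Osteoclast genes had a median of -0.15 (adjusted p = 0.539 with an estimated correlation), and the osteoclast transcription factor Nfatc1 was 8.54 ± 2.36 against 11.9 ± 1.89 FPKM. Cartilage genes had a median of -0.35 (adjusted p = 0.673 with an estimated correlation), and matrix proteases one of -0.27 (adjusted p = 0.673 with an estimated correlation). Wnt signalling, which holds Frzb (log2 difference -1.02), had a median of -0.14 (adjusted p = 0.539 with an estimated correlation). TGF-beta and BMP signalling had one of -0.15 (adjusted p = 0.539 with an estimated correlation), and B cell genes one of -0.27 (adjusted p = 0.673 with an estimated correlation). The Wnt list shares Sost and Dkk1 with the osteocyte list, so those calls are not separate results, and its median gives no direction of signalling. None of the members of these 8 lists passed when adjusted over the list alone. Against sham bones, the knockout DMM medians were -0.02 for osteocyte, 0.07 for osteoblast and bone matrix, 0.05 for osteoclast and -0.2 for cartilage genes. They were 0.33 for matrix protease, -0.03 for Wnt, 0.02 for TGF-beta and -0.25 for B cell genes. Most of the medians against wild-type DMM bones lay closer to 0 without the 3 libraries farthest out on the first principal component, an alternative added after seeing the data. They were then -0.15 for osteocyte, -0.06 for osteoblast and bone matrix, -0.11 for cartilage, -0.13 for matrix protease, -0.05 for Wnt, -0.07 for TGF-beta and -0.08 for B cell genes, none of these lists being called (adjusted p = 0.155 or more). Osteoclast genes had -0.15 and were still called (adjusted p = 0.0181). With array weights, also chosen after seeing the data, the same 7 lists were not called (adjusted p = 0.0529 or more), with medians of -0.25, -0.13, -0.33, -0.07, -0.05, -0.07 and -0.12 in that order. Leaving out 1 library moved medians by over 1.5 times for Wnt genes (-0.08 and -0.09 without knockout replicates 1 and 4), cartilage genes (-0.21 without knockout replicate 4) and osteoblast genes (-0.18 without knockout replicate 4). The matrix protease list was lost with no filter (adjusted p = 0.0671) and the TGF-beta list with the stricter filter (adjusted p = 0.0687).

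Higher in the knockout bones were all 24 oxidative phosphorylation genes, by a small median of 0.13 (adjusted p = 0.539 with an estimated correlation), such as the ATP synthase genes Atp5c1 (log2 difference 0.22) and Atp5a1 (0.15). All 20 fast muscle genes were higher too (median 0.69; adjusted p = 0.673 with an estimated correlation), Ckm being 166 ± 127 against 96 ± 77.3 FPKM. Neutrophil genes had a median of 0.16 (adjusted p = 0.673 with an estimated correlation), megakaryocyte genes one of 0.12 (adjusted p = 0.539 with an estimated correlation) and proliferation genes one of 0.04 (adjusted p = 0.673 with an estimated correlation). Several of these calls were lost when 1 library was left out. Without wild-type DMM replicate 3, 4 of 28 lists were called: the osteocyte, osteoblast and bone matrix, osteoclast, cartilage, matrix proteases and inhibitors, Wnt signalling, TGF-beta and BMP signalling, megakaryocyte and platelet, and proliferation lists then had adjusted p of 0.0814 or more. Their medians were then -0.28, -0.31, -0.14, -0.36, -0.19, -0.18, -0.17, 0.1 and 0 in that order, so the osteoblast, cartilage, Wnt and TGF-beta calls were lost without a smaller median. The medians of fast muscle, neutrophil and oxidative phosphorylation genes were 1.04, 0.26 and 0.23 without that library. The neutrophil list was lost without knockout replicate 1 (median -0.06, adjusted p = 0.599) and without wild-type DMM replicates 1 and 2 (medians 0.03 and 0.12, adjusted p = 0.759 and 0.0651), and its median was 0.29 without knockout replicate 5. It was also lost with the stricter filter, median-of-ratios scaling and the erythroid covariate (adjusted p = 0.0674, 0.0685 and 0.0679) and, in alternatives added after seeing the data, without the 3 far libraries (median -0.02) and with array weights (median -0.13). The B cell list was lost without knockout replicate 1 (median -0.03, adjusted p = 0.595). The fast skeletal muscle list was lost without wild-type DMM replicates 4 and 5 (medians 0.42 and 0.33, adjusted p = 0.051 and 0.0648) and without knockout replicates 3 and 5 (medians 0.37 and 0.43, adjusted p = 0.0869 and 0.0726). Its median was 0.03 with the muscle covariate, which removes it by construction (adjusted p = 0.454), 1.38 without the 3 far libraries and 1.91 with array weights. The matrix protease list was lost without wild-type DMM replicate 1 (adjusted p = 0.125) and without knockout replicates 2 and 4 (medians -0.13 and -0.23, adjusted p = 0.386 and 0.0754). The proliferation list was lost without wild-type DMM replicate 4 (adjusted p = 0.0745) and without knockout replicates 2, 4 and 5 (adjusted p = 0.258, 0.223 and 0.113), and with the stricter filter (adjusted p = 0.155), without the 3 far libraries (adjusted p = 0.848) and with array weights (adjusted p = 0.191). Its median was 0.02 and 0.09 without knockout replicates 2 and 3. The megakaryocyte list was lost without knockout replicate 5 (adjusted p = 0.0613). The other 15 lists had adjusted p of 0.0573 or more, and within them Gdf15 of the senescence list was higher when adjusted over the list alone (1.97 ± 0.312 against 1.2 ± 0.276 FPKM).

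The comparison of knockout DMM with sham wild-type bones differs in both surgery and genotype. Genes that rose were AC117239.2, which shares sequence with Hspe1 as above, and Osm, the cytokine oncostatin M. Osm was 13.5 ± 2.85 FPKM in knockout DMM and 6.07 ± 0.619 in sham bones (SD, n = 5), with a log2 difference of 1.02 (SE 0.13, limma adjusted p = 0.011). It was 9.87 ± 1.51 FPKM in wild-type DMM bones. Gm45222 and Gm26917, unnamed loci given here after their values were seen, rose by log2 differences of 0.53 (adjusted p = 0.0156) and 1.44 (adjusted p = 0.0169).

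These were 4 genes that rose, and 0 fell. At an unadjusted p under 0.05 there were 1430 genes, 797 higher and 633 lower, and the groups did not overlap for 308 genes, or 2.26%, where chance gives 0.79%. The count was 2 without sham replicate 1, without sham replicate 2, without knockout replicate 1 or without knockout replicate 5. It was 7 without knockout replicate 2 and 8 without knockout replicate 4. Gm26917 was lost without sham replicate 1, 2 or 5 or knockout replicate 1 or 5 (adjusted p from 0.0585 to 0.0815). Gm45222 was lost without sham replicate 1, 2 or 3 or knockout replicate 1, 3 or 5 (adjusted p from 0.0529 to 0.0729). In a fit of only the 10 libraries compared, Gm26917 had adjusted p = 0.064 and Gm45222 adjusted p = 0.128. Osm had adjusted p = 0.0513 without the 3 libraries farthest out on the first principal component, an alternative added after seeing the data. Among genes that were lower without passing, Tnf had a log2 difference of -0.68 (adjusted p = 0.0575), Mllt3 one of -0.67 and BC055402 one of -0.6 (adjusted p = 0.0617 for both). Brox had one of -0.82 (adjusted p = 0.171) and Rbm4b one of -0.4 (adjusted p = 0.211). Tnf passed without wild-type DMM replicate 1 (adjusted p = 0.0284), without knockout replicate 4 (adjusted p = 0.0499) and without the 3 far libraries (adjusted p = 0.037). BC055402 passed without wild-type DMM replicate 3 (adjusted p = 0.0495) and without knockout replicate 2 (adjusted p = 0.0225). Tnf, Mllt3 and BC055402 each passed with the muscle covariate (adjusted p = 0.046) and with array weights (adjusted p = 0.00146, 0.0121 and 0.0121). Tnf and Mllt3 passed with the erythroid covariate (adjusted p = 0.0231), Mllt3 and BC055402 with median-of-ratios scaling (adjusted p = 0.0466 and 0.0452), and Brox in a fit of only the 10 libraries compared (adjusted p = 0.00886).

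Camera with the preset correlation called 5 lists higher and 1 lower, and 0 with an estimated correlation. All 13 fibroblast genes were higher than in sham bones (median 0.93; adjusted p = 0.519 with an estimated correlation), and 8 passed when adjusted over the list alone, among them Col3a1, Lum, Col6a2 and Thy1. Of 11 matrix protease genes, 10 were higher (median 0.33; adjusted p = 0.698 with an estimated correlation), and Mmp2, Htra1, Mmp3 and the inhibitor Timp1 passed when adjusted over the list alone. With the muscle covariate, Col3a1 (adjusted p = 0.0348), Lum, Mmp2 and Htra1 (adjusted p = 0.046 each) and Col6a2 (adjusted p = 0.0488) passed over all genes. Thy1, Mmp3 and Timp1 did not, and the count in that setting rests on single libraries. Of 5 tendon genes, 4 were higher (median 0.88; adjusted p = 0.72 with an estimated correlation), and Tnmd, Fmod and Scx passed when adjusted over the list alone. Immediate early and heat shock genes had a median of 0.16 (adjusted p = 0.698 with an estimated correlation), and Dusp1, Fos and Junb were higher when adjusted over the list alone. Over all genes, Dusp1 did not pass in the main fit and passed in 7 of 26 other settings. These were without wild-type DMM replicate 5 and without knockout replicate 4 (adjusted p = 0.0352 and 0.00632), and the stricter filter, median-of-ratios scaling and muscle covariate (adjusted p = 0.0446, 0.0229 and 0.046). Array weights and leaving out the 3 far libraries, added after seeing the data, were the others (adjusted p = 0.00401 and 0.0361). Oxidative phosphorylation genes had a median of 0.1 (adjusted p = 0.914 with an estimated correlation) and B cell genes, such as Pax5 and Cd22, one of -0.25 (adjusted p = 0.914 with an estimated correlation). The B cell list was lost without knockout replicate 1 (median -0.04, adjusted p = 0.618), without sham replicates 2, 3 and 4 (adjusted p = 0.0527, 0.0749 and 0.111), without wild-type DMM replicate 3 (adjusted p = 0.0693) and without knockout replicate 3 (adjusted p = 0.0655). The oxidative phosphorylation list was lost without sham replicates 1 and 4 (adjusted p = 0.191 and 0.117) and without knockout replicates 1 and 4 (adjusted p = 0.181 and 0.0986), its median being 0.04 without knockout replicate 1 and 0.17 without knockout replicate 2. Planned settings ended calls as well: the stricter filter those of the tendon and oxidative phosphorylation lists (adjusted p = 0.304 and 0.107), the erythroid covariate those of the oxidative phosphorylation and B cell lists (adjusted p = 0.213 and 0.129). The B cell list was also lost in a fit of only the 10 libraries compared (adjusted p = 0.0891) and with the muscle covariate (adjusted p = 0.0512). In alternatives added after seeing the data, array weights ended the oxidative phosphorylation and B cell calls (adjusted p = 0.195 and 0.395), and leaving out the 3 far libraries ended both as well (medians 0 and -0.04, adjusted p = 0.798 and 0.5). The tendon and ligament list was lost without sham replicate 4 (median 0.57, adjusted p = 0.0629) and without knockout replicate 3 (adjusted p = 0.107). The immediate early and heat shock (handling) list was lost without knockout replicates 3 and 5 (adjusted p = 0.0655 and 0.0547). Without sham replicate 5, 11 lists were called, and 3 without knockout replicate 3, where matrix protease genes had a median of 0.21. In the inflammatory list, which was not called, Il1b and Cxcl2 were higher and Tnf lower when adjusted over the list alone, and Cxcl2 passed over all genes without knockout replicate 4 (1.52, adjusted p = 6.75e-05). The 22 lists not called had adjusted p of 0.0791 or more; within them Emcn and Adipoq were higher when adjusted over their lists alone.

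**Figure D3:**
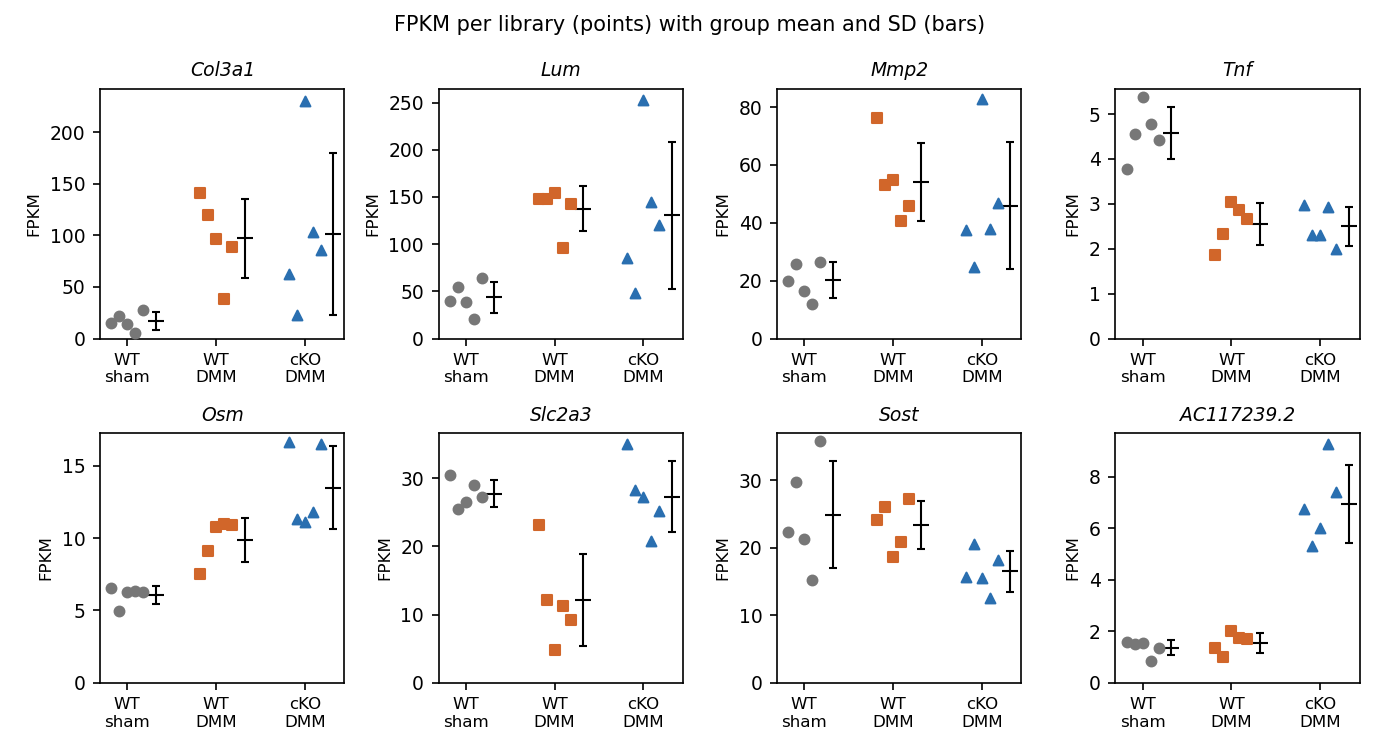
FPKM of 8 genes per library (points) with the group mean and SD (bars) in sham wild-type, DMM wild-type and knockout DMM bones. Tnf was lower in both DMM groups than in sham bones, AC117239.2 was higher in all 5 knockout libraries, and Slc2a3 was 12.1 ± 6.77 FPKM in DMM wild-type and 27.3 ± 5.22 in knockout bones.

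Changes after DMM and changes in the knockout were compared to see whether the genes moved in opposite directions. With the 5 wild-type DMM libraries divided between both comparisons, in 20 ways, the covariance of the log2 differences over genes was 0.007 (SD 0.0167 over the divisions, from -0.0115 to 0.0395). Simulated groups without effects gave 2e-04 ± 0.0133. With all 5 libraries used in both comparisons the covariance was -0.0123 and r across genes was -0.29, and the simulated values were -0.0198 ± 0.0125 and -0.49. Opposition beyond what the shared libraries produce was not seen in these values, and the first covariance was -0.0102 without wild-type DMM replicate 3.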

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

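Tests of Pvalb relative to muscle, of the fibroblast genes and of the splits with the muscle covariate were chosen only after those results were seen; the other split counts and the Nnt tests were set beforehand.

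Across 153 groups of 5 libraries, 7 held a library far from the other 4, where about 8 would be found by chance. The endothelial score was lowest in wild-type DMM replicate 5 (2.85, others 2.95 to 2.98). The slow muscle score was highest in wild-type DMM replicate 3 (2.07, others 0.654 to 0.932), which also had the fewest gene IDs above 0 in its group (25400, rounded; others 26400 to 26600). In knockout replicate 1 the erythroid score was 8.12 (others 9.09 to 9.43) and the B cell score 2.9 (others 3.89 to 4.11). The FPKM total was highest in knockout replicate 4 (468000, rounded; others 388000 to 409000). Osm was lowest in sham replicate 2 (4.98 FPKM, others 6.26 to 6.52).

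Pvalb was low for its muscle level in the knockout libraries, and muscle carried with the bone may set most of the Pvalb level, since its log2 level followed the fast muscle score with r = 0.93. A general fall of fast muscle genes relative to Ckm is argued against: the other 19 genes changed by a median of -0.12 (SD 0.21, lowest -0.65), while Pvalb changed by -1.12 (95% interval -1.5 to -0.73). Loss in bone alone, with a bone share alike in all wild-type libraries, is argued against: with that share left free and none in the knockout, log2 Pvalb for its Ckm was lower in the knockout by -1.04 (95% interval -1.47 to -0.6), and the interval lay below 0 with each library left out (highest end -0.48, without knockout replicate 1). That test was added after an earlier one on the FPKM scale had missed its bound, in which the slope of Pvalb on Ckm differed by -0.55 (95% interval -0.98 to -0.12) but the interval reached 0 without knockout replicate 3 (-0.46, from -1.06 to 0.14). Reduced Pvalb in the muscle fibres of the knockout, for instance from Cre activity there, or another mix of fibres may account for it, and neither was tested. Relative to Ckm, the fast myosin genes Myh4, Myh1 and Myh2 changed by -0.04, -0.19 and -0.65, each less than Pvalb.

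Fibroblast and tendon genes were higher after DMM in wild-type bone. A smaller share of marrow as the whole cause is argued against only weakly. The fibroblast score minus the mean of the cartilage and endothelial scores went from 0.21 in sham to 1.23 in DMM bones, a change of 1.02 (exact permutation p = 0.0159). That reference is limited, since marrow holds endothelial cells too and the cartilage score spread widely in sham bones (4.4 ± 0.74). The osteoblast and bone matrix score, which is outside that reference, rose by 0.42 and the fibroblast score by 1.2. Soft tissue left in step with muscle is argued against as the whole cause: at equal muscle score the fibroblast score was higher after DMM by 1.39 (95% interval 0.9 to 1.88; exact permutation p = 0.00794), and the interval stayed above 0 with each library left out (lowest 0.63, without sham replicate 4). That test was added after the fit with the muscle covariate was seen and after an earlier test had not passed, in which the fibroblast score minus the muscle score went from -1.34 in sham to 0.64 in DMM bones, a change of 1.98 (exact permutation p = 0.0635), and with the tendon genes included the 2 changes were 0.95 for marrow (exact permutation p = 0.0238) and 1.91 for muscle (exact permutation p = 0.0635). More fibrous tissue left at dissection without more muscle and a response of the joint to DMM may both account for the rise, and the design does not separate them.

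The gene IDs named Nnt, which encodes a mitochondrial transhydrogenase, changed places in some knockout libraries. ENSMUSG00000116207 was listed at 0, 2.26, 0, 5.37 and 6.94 FPKM in knockout replicates 1 to 5 and between 5.88 and 8.32 in wild-type libraries, while ENSMUSG00000025453 was 3.76, 2.81, 7.5, 0.557 and 0.546 FPKM. Reads moved between the models remain possible, since all 3339 exonic bases of the first are shared with the second; 0 other genes with a median of at least 5 FPKM showed such zeros, which met the bound set beforehand against this explanation, but 13 other symbols with several IDs at that level are too few for that bound, a judgement made after seeing it. Whether a segment of another strain surrounds the floxed Pvalb allele was not settled: 0 of the 100 tested genes around Pvalb had p under 0.01. That met the bound set beforehand, but the median of other windows was also 0, so that bound could not count against a segment. The window was set around Pvalb and not around Nnt, so it does not bear on the Nnt IDs. A strain difference at Nnt itself may be involved and was not tested.

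Other splits of the 10 libraries in each comparison, 100 of the 126 possible, bear on whether chance can be excluded. For DMM against sham the real count was 0 genes, which all 100 splits reach by construction (highest other 2), so the splits decide nothing there. For the 13 lists, 28 splits gave as many (highest other 20), so chance is not excluded. With the muscle covariate, 1 of 100, the real one, reached 280 genes (highest other 7). Chance is less likely for that count but not excluded. The setting gave the largest count of the 29 other settings tried, and the splits did not repeat that choice. The count was 59 without sham replicate 4. For knockout against wild-type, 14 splits reached 1 gene (highest other 2625), 10 reached 13 lists (highest other 16) and 12 reached 1 gene with the covariate (highest other 4731), so chance is not excluded for these counts. A count of 1 does not bear on which gene it is: AC117239.2 was 5.29 to 9.26 FPKM in the knockout and 0.857 to 2 FPKM in all 10 wild-type libraries, and it passed in all 26 alternatives (adjusted p from 1.28e-05 to 0.00596). The split with 2625 genes put knockout replicates 1 and 4 with wild-type DMM replicate 3, the 3 libraries far out on the first principal component, which points to a structure among libraries other than genotype. For knockout DMM against sham, 86 splits reached 6 lists (highest other 20), so chance is not excluded for the lists. For genes, 2 splits, the real one among them, reached 4 (highest other 225). With the covariate 1, the real one, reached 21 (highest other 1). Chance is less likely for both gene counts, but 100 splits do not exclude it. Both counts rest on single libraries: the 4 became 2 without sham replicate 1 or 2 or knockout replicate 1 or 5, 7 without knockout replicate 2 and 8 without knockout replicate 4. The 21 ran from 1, without sham replicate 1 or 4, to 60, without knockout replicate 2. It was also 2, 4 and 4 without sham replicates 2, 3 and 5, 6 and 8 without wild-type DMM replicates 2 and 5, and 3, 4, 8 and 9 without knockout replicates 1, 3, 4 and 5. The split with 225 genes points to a structure of the libraries: it put knockout replicates 1, 2 and 4 with sham replicates 1 and 4, the 5 libraries with the lowest fast muscle scores of the 10 (2.32 to 4.63, others 5.87 to 6.81), and it gave 0 genes with the muscle covariate.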

How the results depend on the processing

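Array weights, the 3 far libraries left out, library-score permutation, fry, the ratio to Ckm, Ckm alone and the muscle covariate with an estimated correlation were tests chosen after results were seen; the cause of a change was not tested unless stated. DMM against sham (0 genes) gave 2 with no filter, 280 with the muscle covariate, 1 with the erythroid covariate, 15 with array weights, 247 with Ckm alone and 0 to 2 with a library left out. Knockout against wild-type (1) gave 2 with no filter, 4 with array weights and 1 to 2 with a library left out. Knockout DMM against sham (4) gave 7 with no filter, with median-of-ratios scaling and without the 3 far libraries, 9 at adjusted p under 0.1, 21 with the muscle covariate, 22 with array weights and 2 to 8 with a library left out. Genes named by rule that passed (3) became 5 with scaling, 15 with the muscle covariate, 6 with the erythroid covariate, 13 with array weights and 3 to 5 with a library left out.

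The replicate block gave 1 gene for knockout DMM against sham and changed no other count of genes or lists by over 1.5 times; Osm, Gm26917 and Gm45222 then had adjusted p = 0.0767, 0.0806 and 0.118. The numbers do not pair the libraries: 6 of 15 same-number pairs correlated over 0.1 (range -0.46 to 0.4), and 2 of 15 libraries were closest to their own number.

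Called lists (13, 13 and 6 in the order above) fell to 0 in each comparison with an estimated correlation, with library-score permutation and with the muscle covariate and an estimated correlation. The permutation could hardly give a call, so its 0 decides little. Its smallest possible p was 0.0079, and the matrix protease list after DMM, at that limit, had a permutation adjusted p = 0.173 over the 28 lists. Fry called 2, 0 and 0. Array weights gave 5 for knockout against wild-type; without the 3 far libraries it was 6, and 11 for knockout DMM against sham. With a library left out they ranged from 4 to 16 for knockout against wild-type and from 3 to 11 for knockout DMM against sham. The fast muscle median after DMM turned to 0.06 with the muscle covariate, which removes it by construction. In the knockout the neutrophil median was -0.13 with array weights and -0.06 to 0.29 with a library left out. Oxidative phosphorylation in knockout DMM against sham came to 0 without the far libraries.

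Pvalb after DMM turned to 0.22 with the muscle covariate and 0.19 relative to Ckm. In the knockout it was 1.04 with array weights, 0.44 without the far libraries, -1.23 relative to Ckm and -0.74 to 0.13 with a library left out. S100a8 in the knockout was -0.15 with array weights, -0.01 without the far libraries and 0 to 0.36 with a library left out; Cebpe was -0.05 with array weights. Slc2a3 in knockout DMM against sham (-0.04) was 0.01 with the erythroid covariate and -0.13 to 0.05 with a library left out. Over 2906 recomputations of named genes 2807 kept direction and side of the threshold, 17 lost the call, 76 gained it and 6 turned; over 864 of called lists these were 747, 113, 0 and 4. The covariance was -0.0123 with all 5 libraries in both comparisons, which shared libraries lower by construction, and -0.0102 to 0.0158 with a library left out. Depth was unknown, so its effect on precision could not be given.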

Other observations

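Slc2a3 in the knockout, Gm26917 and Hspe1 were picked for this section after their values were seen. The limma fit and the settings with a library left out were fixed in advance, and array weights were not. Slc2a3, a glucose transporter, was 27.8 ± 2.01 FPKM in sham wild-type, 12.1 ± 6.77 in DMM wild-type and 27.3 ± 5.22 in knockout DMM bones (SD, n = 5). Its log2 difference between knockout and wild-type after DMM was 1.24 (SE 0.27, limma adjusted p = 0.935) and did not pass the test. It passed in 2 of the settings tried, without wild-type DMM replicate 1 (1.5, adjusted p = 0.0289) and with array weights (1.18, adjusted p = 0.045), and in the others adjusted p was 0.334 or more. That library had 23.1 FPKM and the other wild-type DMM libraries 4.85 to 12.2. Gm26917, a long noncoding locus, was 67.1 ± 14.6 FPKM in sham, 164 ± 40.4 in DMM wild-type and 186 ± 52.9 in knockout DMM bones. Hspe1, the near-identical copy of AC117239.2, was 46.5 ± 9.71 FPKM in knockout and 38.8 ± 13.2 in wild-type DMM bones (log2 difference 0.28, adjusted p = 0.935).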
